A study of Mus musculus with 16 samples.

How the data were processed

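The samples were naive CD4+ or CD8+ T cells (CD25-negative, CD62L high, CD44 low) sorted from lymph nodes of C57BL/6 mice into the third with the highest (CD5hi) and the third with the lowest (CD5lo) surface CD5. Groups were taken from the labels: 4 groups of 4 biological replicates, 16 samples. The design text names 2 technical replicates per sample, but each sample has 1 column of values, so technical runs were not compared. Per the labels' protocols, RNA was isolated with TRIzol and RNeasy, and libraries were made with the TruSeq RNA v2 or the TruSeq stranded mRNA kit. Which kit each sample had, and the strand setting of the counting, are not given in the sources used here. Per the submitters' processing notes, tools named were STAR 2.5.2a, featureCounts 1.4.6-p3 and DESeq2, with the assembly mm10.

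The values used were the deposited counts, 1 table of integers with 24421 genes and a column per sample, which the authors had not normalised as far as the values show. All columns were matched to a sample (0 left over). The table was checked: 6123 genes had 0 counts in every sample, 27 names had been turned into dates (0.263% of counts) and were kept under the name given, and 4 entries shared a name with another. Counts from 1 to 9 were even in 73.9 to 80.5% of cases, against 49.2 to 51.3% of counts of 1000 or more. Halving all counts was therefore added as an alternative after the data were seen. Totals ran from 71447252 to 93418385 counts (median 78528233). The 10 most abundant genes held 4.61 to 5.20% of counts, and normalisation factors ran from 0.981 to 1.017. No library was a copy of another of its group (chi-square per degree of freedom for each pair of libraries within a group 33.5 to 246).

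Genes were tested with edgeR 4.0.16 in R 4.3.3: TMM normalisation, the filterByExpr filter (minimum count 10, minimum total 15), 1 term per group over all 16 samples (12 residual degrees of freedom), and the quasi-likelihood F test. The filter left 13554 genes. Comparisons were CD5hi against CD5lo in CD4 cells and in CD8 cells, the difference between these effects (interaction), and CD8 against CD4 cells at low and at high CD5. P-values are two-sided and adjusted by Benjamini-Hochberg over all genes within each of these 5 comparisons, with a threshold of 0.05; the SE of a log2 change is its size over the square root of F. CPM values are TMM-normalised counts relative to library size, given as mean and SD of 4 libraries. Genes called in both lineages were compared with chance by Fisher's exact test.

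Gene lists, the comparisons, the rule for naming genes and the alternatives not marked otherwise were fixed before the data were examined. Of the lists, 31 had at least 5 tested members and were tested by camera (limma 3.58.1) on voom log2 CPM with a preset correlation between genes of 0.01, adjusted over the 31 lists. Camera compares a list with all other genes. It was also run with the correlation estimated for each list, and fry tested whether the genes of a list move on balance one way, without comparing them with other genes. With an estimated correlation and all 16 libraries, the lists that kept their call were regulatory T cell genes, follicular helper and anergy genes, negative regulators of T cell receptor signalling and BCL2 family genes, all in CD4 cells. Lists of mitochondrially encoded genes and of T cell receptor V and J segments had 0 tested members and that of erythroid and platelet markers 1, so they were not tested.

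The rule for naming genes took, for each CD5 comparison, the 12 largest changes each way among genes with adjusted p under 0.05, a mean of at least 5 CPM and no overlap between groups. For the interaction it took 8 each way without the overlap condition, and for each lineage comparison 6 each way. It added up to 4 members with the smallest adjusted p per list, and always Cd5, Cd4, Cd8a, Cd8b1, Cd44, Il2ra, Nfkbia, Nfkb1, Nfkb2, Rela, Relb and Rel; 1 further gene of this fixed set is not reported here. Predicted genes, clone names and T cell receptor and immunoglobulin segments were left out of the ranking. Foxp3, Tbx21 in CD8 cells, Cd74, Bcl3, Xist and Ddx3y were chosen after their values were seen. Gene positions come from GENCODE vM21 (GRCm38, 1-based). Of the 127 genes named, 17 share exonic bases with another tested gene. In 2 of them a single other tested gene covers at least 10% of the exonic bases: Abhd15 (10.8%) and Foxp3 (12.9%).

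The procedure was tested on simulated data, with 200 changed genes of 13554. Of genes changed 2-fold, 74.6% were called in the CD4 comparison, 67.2% in CD8 and 50.7% in the interaction, and of those changed 1.5-fold 55.2, 41.8 and 22.4%. Unchanged genes called numbered 3, 8 and 7, and 0 of 31 unchanged lists were called. The simulated genes varied independently, the lists were random, and no replicate effects or libraries rich in B cell markers were included. The simulation therefore does not test camera's preset correlation on lists whose genes move together. 

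Alternatives were RLE size factors, no filter on low counts, DESeq2 1.42.0, limma voom, a fit of only the groups compared, a threshold of 0.01, a term for the replicate number, each library left out in turn, and the list tests named above. The replicate numbers come from the labels, which do not say what equal numbers share. By their deviations from group means across genes, the 4 same-numbered pairs of libraries all correlated over 0.1 between CD4 CD5lo and CD5hi (0.251 to 0.534), between CD4 and CD8 at low CD5 (0.203 to 0.704) and at high CD5 (0.235 to 0.538). In these 3 comparisons the numbers were taken to pair the libraries, and values with the replicate block are given where they change a call or move a count by over 1.5 times. Between CD8 CD5lo and CD5hi 2 of 4 pairs did so, and each of the others holds a library rich in B cell markers. For CD8 CD5hi against CD5lo and the interaction only the counts with the block are given. Without the 3 libraries rich in B cell markers (mean log2 CPM of the markers at least 2 above every other library of their group), all comparisons were run again, as chosen after the data were seen. Each count was also set against other splits of the same samples. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 was used for positions and figures.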

Results

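RNA sequencing measured gene expression in naive T cells from the lymph nodes of C57BL/6 mice, sorted by how much CD5 they carried on the surface. CD5 is a receptor that restrains T cell receptor signalling, and its level on a naive T cell is set by how strongly that cell recognises self ligands. Cells that lacked CD25, with high CD62L and low CD44, were gated as CD4+ or CD8+, and the third of each with the most CD5 (CD5hi) and the third with the least (CD5lo) were collected. Each of the 4 groups had 4 biological replicates, 16 libraries in all; whether replicates came from separate animals is not given in the sources used here. By its title the study concerns CD5 and basal NF-kB signalling, so genes of that pathway are given for each comparison. Libraries held 71447252 to 93418385 counts, with a count for 14455 to 15991 genes. Of all genes, 13554 were tested. The leading axis of variation (47.1% of variance) separated CD4 from CD8 libraries without overlap.

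The genes behind the sort followed the gates. Cd5 RNA averaged 255 ± 19.5 CPM in CD4 CD5lo, 1386 ± 34.4 in CD4 CD5hi, 200.4 ± 12.3 in CD8 CD5lo and 498 ± 37.8 in CD8 CD5hi (counts relative to library size, mean ± SD, n = 4 libraries each). Cd4 was at 1159 and 1023 CPM in the CD4 groups, and Cd8a at 1979 and 1604 CPM in the CD8 groups. Cd44 lay between 5.81 and 14.6 CPM in all 4 groups, and Il2ra, which encodes CD25, between 1.45 and 5.43 CPM. In 3 libraries, CD4 CD5lo replicate 3, CD8 CD5lo replicate 3 and CD8 CD5hi replicate 4, B cell markers stood apart. Cd74, the invariant chain of MHC class II, was at 134.8, 192 and 319.5 CPM there and at 16.5 CPM or less in the other 13. Of these, the CD8 libraries also held Cd4 at 27.2 and 62.2 CPM, against at most 2.51 CPM in the other CD8 libraries. The CD4 library held Cd8a at 11.4 CPM, against at most 5.49 in the other CD4 libraries. The counts of changed genes in each comparison and in both lineages are therefore given also without these 3 libraries, an alternative chosen after the data were seen.

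**Figure D1:**
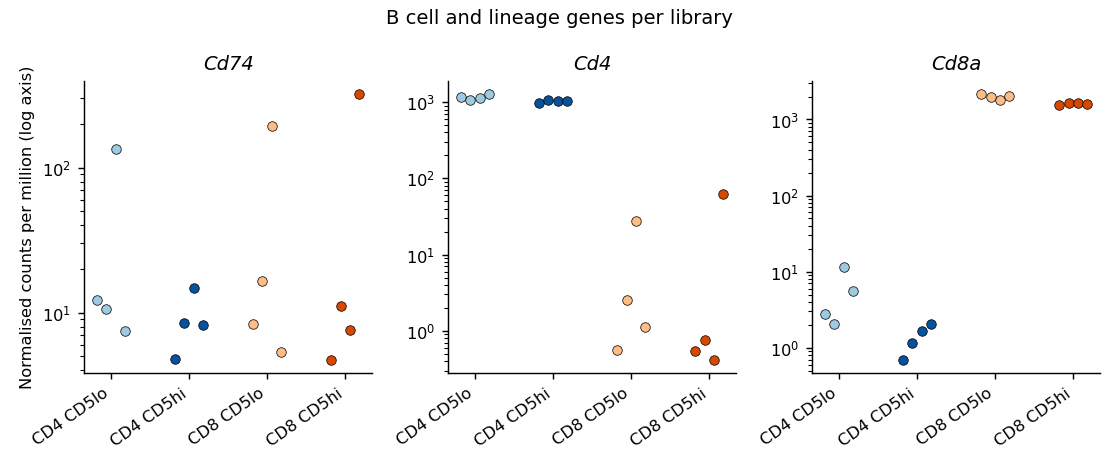
RNA of the B cell marker Cd74 and of the lineage genes Cd4 and Cd8a in the 16 libraries (CPM on log axes), grouped by lineage and CD5 level, 1 point per library. In CD4 CD5lo replicate 3, CD8 CD5lo replicate 3 and CD8 CD5hi replicate 4, Cd74 reached 134.8, 192 and 319.5 CPM, against at most 16.5 in the other 13.

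In CD4 cells, high CD5 went with more RNA of Cd5 itself, of its sister receptor Cd6, and of 10 of the 17 genes on the regulatory T cell list. Cd5 rose by 2.44 ± 0.07 on the log2 scale (± SE; edgeR adjusted p = 3.33e-12) and Cd6 by 2.01 ± 0.07, from 358 ± 28.5 to 1437 ± 62.7 CPM (adjusted p = 2.63e-11). Cd5 and Cd6 lie on the same strand of chromosome 19, 50338 bp apart. The widest rises by the ranking used were those of the potassium channel subunit Kcnf1 (4.46 ± 0.58, to 28.6 CPM in CD5hi), the inter-alpha-trypsin inhibitor chain Itih5 (3.71), the Rac GTPase-activating protein Chn2 (2.96) and the cation channel Trpm1 (2.87). Next came the costimulatory receptor Tnfrsf9 (4-1BB; 2.79 ± 0.14, from 2.79 to 19.35 CPM), the transcription factor Ikzf2 (Helios; 2.63) and Phactr2 and the coronin Coro2a (both 2.45). Also among the 12 were Izumo1r (folate receptor 4; 2.43), the semaphorin receptor Nrp2 (2.14) and Nt5e (CD73; 2.09). The widest falls by that ranking were those of the metalloprotease Adamts14 (fell by 2.21), the glutamate receptor Grm6 (fell by 2.16), and the gut-homing receptor Ccr9 (fell by 1.98, from 36.4 to 9.26 CPM). They went on with the potassium channel Kcna2 (fell by 1.96), Pdlim4 (fell by 1.87), the transporter Slc16a5 (fell by 1.84) and the CD8 chain Cd8b1 (fell by 1.82, from 28.15 to 7.996 CPM). The last of the 12 were carbonic anhydrase Car2 (fell by 1.74), Adam6b (fell by 1.70), the kinesin Kif23 (fell by 1.43), Abhd15 (fell by 1.37) and Sytl3 (fell by 1.33). Dntt, the terminal transferase of developing lymphocytes and a member of the thymocyte list, fell by 2.65. Of the 13554 genes, 363 were higher and 190 lower in CD5hi, 160 and 62 of them by at least 2-fold. Without the 3 libraries the counts were 366 and 168, with 193 and 62 by at least 2-fold, and 429 of the 553 genes were called again. With the replicate number as a block they were 771 and 541.

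Genes of the regulatory T cell list rose as a group in CD4 CD5hi. Of 17 measured members, 10 rose and 7 did not pass over all genes, with 12 higher and 1 lower adjusted over the list alone. Their median was 1.46 (camera adjusted p = 2.63e-22, and adjusted p = 0.00202 with an estimated correlation). Examples were Tnfrsf9, Izumo1r, Nt5e and the receptor Gpr83 (1.71 ± 0.15). Foxp3, which specifies regulatory T cells and was singled out after its values were seen, rose by 1.81 ± 0.47 (adjusted p = 0.0370), from 4.96 to 17.45 CPM. That call was lost without any 1 of the 8 CD4 libraries (adjusted p from 0.0611 without CD4 CD5hi replicate 1 to 0.114 without CD4 CD5lo replicate 1). The SE is estimated over all 16 samples, so it also draws on the CD8 libraries. Foxp3 was at 4.16 CPM in CD8 CD5lo replicate 3, against at most 1.70 in the others of its group. In CD8 CD5hi replicate 4 it was at 8.31 CPM, against at most 2.35. Leaving out single CD4 libraries keeps these CD8 libraries in the fit. Without the 3 libraries rich in B cell markers Foxp3 rose by 1.91 ± 0.20 (adjusted p = 5.24e-05). The log2 change of Il2ra, the gated CD25, was 1.13 ± 0.56 (adjusted p = 0.434), and leaving out the 3 libraries it rose by 1.32 ± 0.32 (adjusted p = 0.0327). Of 16 follicular helper and anergy genes, some of them on both lists, 6 rose and 10 did not pass (9 higher adjusted over the list alone). This list had a median of 0.67 (camera adjusted p = 1.93e-13, and adjusted p = 0.00245 with an estimated correlation). With the replicate block added to an estimated correlation that call was lost (adjusted p = 0.0845). The inhibitory receptor Pdcd1 (PD-1) rose by 1.98 and Cd200 by 1.91. Of 28 negative regulators of T cell receptor signalling, 7 rose and 2 fell (11 and 4 adjusted over the list alone). Here camera gave an adjusted p = 7.10e-06, and adjusted p = 0.00245 with an estimated correlation. Besides Cd6, Pdcd1 and Cd200, the phosphatase Ubash3b rose by 1.31, while the cytokine signalling inhibitor Socs3 fell by 0.87. Of 15 BCL2 family genes, 3 rose and 12 did not pass (5 higher and 2 lower adjusted over the list alone). For them camera gave an adjusted p = 0.00325, and adjusted p = 0.0279 with an estimated correlation, a call lost when the replicate block was added to the latter (adjusted p = 0.108). The 3 were Bcl2a1d (1.63) and Bcl2a1b, near-identical survival genes between which reads can be shared, and the pro-apoptotic Bcl2l11 (BIM; 0.65). With the replicate block, 11 negative regulators rose and 4 fell, and 6 BCL2 family genes rose and 2 fell. B cell markers went the other way from these lists (median -2.58), and the regulatory T cell list had a median of 1.68 with 13 members higher without the 3 libraries.

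RNA of the NF-kB genes themselves showed little difference between CD4 CD5hi and CD5lo. These data do not measure protein levels or NF-kB activity. Nfkbia, which encodes the inhibitor IkB-alpha, was at 350.1 ± 101.7 and 336 ± 72.9 CPM (log2 change -0.06 ± 0.23, adjusted p = 0.991). Log2 changes of the subunit genes were 0.15 ± 0.06 for Nfkb1 (adjusted p = 0.241) and -0.17 for Nfkb2 (adjusted p = 0.865). They were -0.05 for Rela (adjusted p = 0.989), 0.09 for Relb (adjusted p = 0.944) and 0.00 ± 0.34 for Rel. With an SE of 0.23 for Nfkbia and 0.34 for Rel, moderate changes in these genes are not excluded. Of 31 pathway genes, 1 passed, also adjusted over the list alone: Malt1, the paracaspase that couples antigen receptors to NF-kB, rose by 0.34 ± 0.08 (adjusted p = 0.0254), from 148 to 188 CPM. That call was lost without CD4 CD5lo replicate 1, 3 or 4 (adjusted p = 0.0711, 0.0586 and 0.0877) or CD4 CD5hi replicate 1, 2 or 3 (adjusted p = 0.0887, 0.1103 and 0.0602). With the replicate block 2 pathway genes passed, Malt1 and Bcl3, which encodes an atypical IkB protein (0.48 ± 0.11, adjusted p = 0.0122; 0.50 and adjusted p = 0.598 without the block). The pathway list as a whole had a median of -0.01 and a camera adjusted p of 0.982. Of 34 NF-kB target genes, 4 rose and 2 fell (5 and 2 adjusted over the list alone). They had a median of -0.07 but a mean of 0.20, and camera gave their direction as up (adjusted p = 0.351). Tnfrsf9, Bcl2a1d, Bcl2a1b and the costimulatory receptor Tnfrsf4 (OX40; 0.82) rose, and the adaptor Traf1 fell by 0.60. Of 25 genes induced early by T cell receptor signals, 4 rose and 21 did not pass (5 higher and 2 lower adjusted over the list alone). Their median was -0.08, their mean 0.11 and camera's direction up (adjusted p = 0.199). Tnfrsf9 was among them, as was Nab2 (0.49), whose call was lost without CD4 CD5hi replicate 1 (adjusted p = 0.0516). Camera's adjusted p without the 3 libraries was 0.0191 for the targets and 0.0115 for the early genes, and both had an adjusted p of 0.402 with an estimated correlation.

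**Figure D2:**
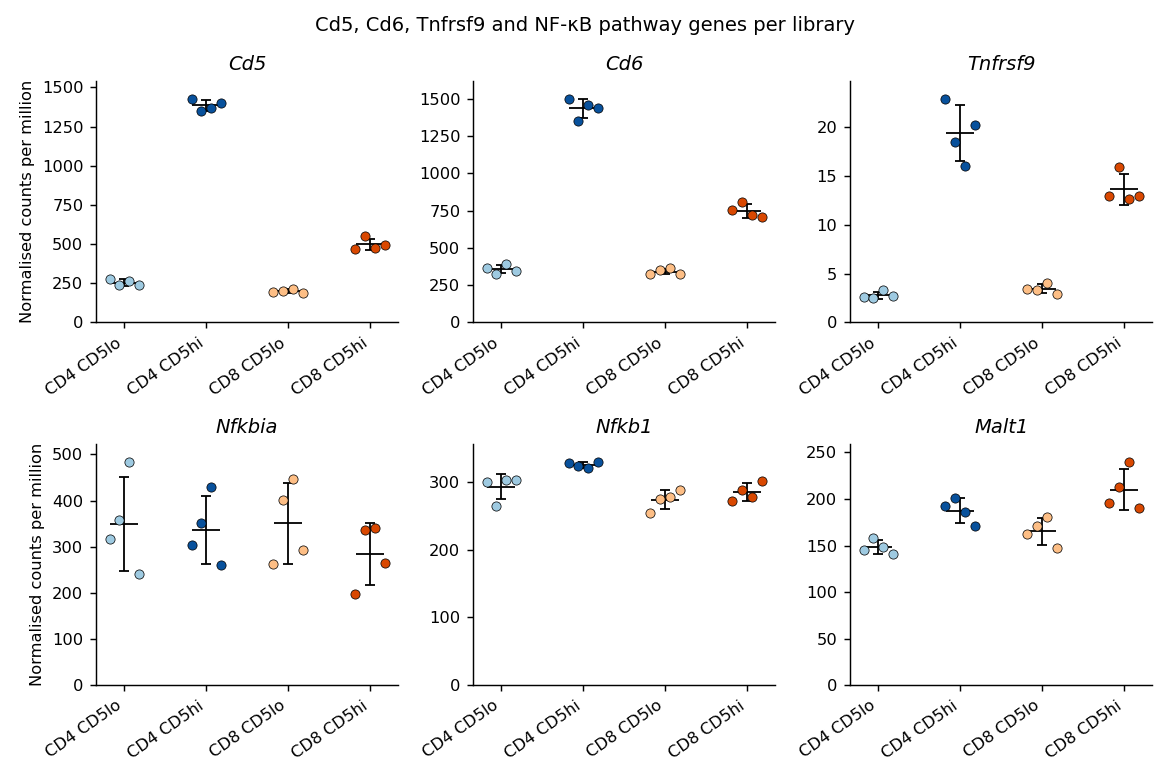
Cd5, Cd6, Tnfrsf9, Nfkbia, Nfkb1 and Malt1 in each library (CPM), with points for the 4 libraries of each group and the mean ± SD. Cd5 averaged 255 and 1386 CPM in CD4 CD5lo and CD5hi, and Nfkbia 350.1 and 336 CPM.

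Groups lower in CD4 CD5hi lost their call with an estimated correlation. Of 8 CD8 lineage genes, 4 fell and 1 rose (5 and 1 adjusted over the list alone). Their median was -0.75 (camera adjusted p = 0.00191, and adjusted p = 0.214 with an estimated correlation). Besides Cd8b1, Cd8a fell by 1.97 ± 0.42 (adjusted p = 0.0122), from 5.43 to 1.39 CPM, with 11.4 CPM in CD4 CD5lo replicate 3, the library rich in B cell markers. Without that library it fell by 1.31. The adhesion molecule Crtam fell by 0.61. Of 45 interferon-stimulated genes, 6 fell and 39 did not pass (6 adjusted over the list alone; camera adjusted p = 0.00506, and adjusted p = 0.876 with an estimated correlation). Among them were the GTPases Igtp, which fell by 0.48 ± 0.06, and Gbp2, which fell by 0.40. Of 22 handling stress genes, 1 fell, and 2 did so adjusted over the list alone (camera adjusted p = 0.000880, and adjusted p = 0.271 with an estimated correlation). It was the antiproliferative gene Btg2, which fell by 0.36 (adjusted p = 0.0499). This call was lost without any of 6 single libraries, with adjusted p up to 0.1497 without CD4 CD5hi replicate 2. None of 82 ribosomal protein genes passed in edgeR (2 were lower at an unadjusted p under 0.05, 0 by DESeq2 and 0 by limma voom). They had a median of -0.07 (camera adjusted p = 0.000822, and adjusted p = 0.876 with an estimated correlation). None of 24 cell cycle genes passed in edgeR either (4 were higher at an unadjusted p under 0.05, 0 by DESeq2 and 0 by limma voom). Here the median was 0.21 (camera adjusted p = 0.0245, and adjusted p = 0.876 with an estimated correlation). With the replicate block 4 handling stress genes and 2 ribosomal protein genes fell, and 3 cell cycle genes rose. Of 33 effector and memory genes, 6 rose and 4 fell (6 and 5 adjusted over the list alone; camera adjusted p = 0.519). The cytokine receptor chain Il2rb rose by 1.92 and the T-box factor Eomes by 1.24, while granzyme gene Gzma fell by 3.03 and perforin gene Prf1 by 0.98. Beside these groups, the B cell marker list had a median of -2.58 (camera adjusted p = 0.0123, and adjusted p = 0.876 with an estimated correlation). None of its 16 genes passed in edgeR (1 lower at an unadjusted p under 0.05, 0 by DESeq2 and 0 by limma voom), and without the 3 libraries its median was -0.62. The 14 myeloid and 7 natural killer cell markers had medians of -1.07 and -0.92, with camera adjusted p of 0.0771 and 0.106.

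In CD8 cells, high CD5 went with more RNA of Cd5 and Cd6, of 21 of 24 cell cycle genes, of 7 of 33 effector and memory genes, and of 209 of the 363 genes that were higher in CD4 CD5hi. As groups, the cell cycle and the effector and memory lists had adjusted p = 0.142 each with an estimated correlation, so their calls by camera were lost. Cd5 rose by 1.31 ± 0.07 (edgeR adjusted p = 2.61e-08) and Cd6 by 1.13 ± 0.07, from 342 to 748 CPM (adjusted p = 1.09e-07). The widest rises by the ranking were those of Kcnf1 (4.58), Itih5 (3.66), Chn2 (2.51), the microtubule regulator Stmn1 (2.45 ± 0.27, from 5.69 ± 1.41 to 31.01 ± 12.4 CPM) and the proliferation antigen Mki67 (2.42, from 10.96 to 58.7 CPM). Then came Coro2a (2.39), Tnfrsf9 (1.98), the calcium-binding annexin Anxa2 (1.94), the thioesterase Acot7 (1.86), the topoisomerase Top2a (1.84) and Ndrg1 (1.84). Samd3 rose by 2.23 (adjusted p = 0.0337), a call lost without any of 6 single libraries (highest adjusted p 0.108 without CD8 CD5hi replicate 1). The chemokine Xcl1, of the effector list, rose by 3.43 ± 0.47, from 1.09 to 11.7 CPM. The widest falls were those of the amino acid transporter Slc6a19 (fell by 3.20 ± 0.33, from 36.4 ± 7.87 to 3.96 ± 1.37 CPM), Grm6 (fell by 3.01), Adamts14 (fell by 2.67) and Pdlim4 (fell by 2.12). Next were Osgin1 (fell by 1.89), Slc16a5 (fell by 1.72), the cytochrome P450 Cyp2s1 (fell by 1.70). The rest were Dmbt1 (fell by 1.65), Tmie (fell by 1.48), Igsf23 (fell by 1.47), the pro-apoptotic Bmf (fell by 1.39) and Kcna2 (fell by 1.36), while Dntt, of the thymocyte list, fell by 2.94. Of the 13554 genes, 806 were higher and 476 lower, 293 and 85 of them by at least 2-fold. There were 946 and 546 without the 3 libraries, with 404 and 110 by at least 2-fold, and 1083 of the 1282 were called again. The replicate block gave 1813 and 1577, where not every pair of libraries shows the pairing. The counts moved with single libraries. Without CD8 CD5hi replicate 2 they were 518 and 252. The lower count was 310, 312 and 256 without CD8 CD5lo replicates 1, 2 and 4, and it was 312 without CD8 CD5hi replicate 3.

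By gene list, camera with its preset correlation called 9 lists higher and 3 lower in CD8 CD5hi, fry called 7 and 1, and camera with an estimated correlation called 0 (7 higher and 0 lower at an unadjusted p under 0.05). The list fry called lower was proximal T cell receptor signalling, which is not among the 3 that camera called lower. The cell cycle list had the largest median change of the lists called. The lists called lower fell to 1 without CD8 CD5lo replicate 3 and to 1 without CD8 CD5hi replicate 2. Of 24 cell cycle genes, 21 rose and 3 did not pass (23 higher adjusted over the list alone). Their median was 1.58 (camera adjusted p = 2.32e-20, and adjusted p = 0.142 with an estimated correlation). The replication helicase genes Mcm5, Mcm3 and Mcm2 rose by 1.02, 0.90 and 0.71, and thymidine kinase Tk1 by 1.69. Of 33 effector and memory genes, 7 rose and 2 fell (13 and 3 adjusted over the list alone). These had a median of 0.58 (camera adjusted p = 1.01e-05, and adjusted p = 0.142 with an estimated correlation). Besides Xcl1 and Anxa2, Eomes rose by 1.41, from 43.2 to 115 CPM, and the integrin chain Itgb1 by 0.56. Tbx21 (T-bet), singled out after its values were seen, rose by 2.76, from 2.12 to 14.3 CPM. Cd44, the memory marker held low by the gate, rose by 1.33 ± 0.36 (adjusted p = 0.0268), from 5.81 to 14.6 CPM. Its call was lost without CD8 CD5lo replicate 1 or 4 (adjusted p = 0.0589 and 0.0769) or CD8 CD5hi replicate 1 or 2 (adjusted p = 0.0798 and 0.1005). In the same contrast the B cell markers had a median of 0.50 while camera gave their direction as down (adjusted p = 0.721), and the 14 myeloid markers a median of 0.30 (camera adjusted p = 0.547). Without the 3 libraries the cell cycle list had 23 genes higher and a median of 1.85 (adjusted p = 0.0381 with an estimated correlation). The effector list then had 15 higher and 2 lower and a median of 0.82 (adjusted p = 0.0808 with an estimated correlation). The B cell markers were then called lower by camera with its preset correlation (median -0.55, adjusted p = 0.0448, and adjusted p = 0.785 with an estimated correlation).

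Camera with its preset correlation also called the glycolysis, ribosomal protein and respiratory chain lists higher in CD8 CD5hi, though few of their genes passed. All 3 calls were lost with an estimated correlation (adjusted p = 0.116, 0.644 and 0.646). Of 17 glycolysis genes, 6 rose and 11 did not pass (7 higher adjusted over the list alone). Their median was 0.25 (camera adjusted p = 3.64e-05). Triosephosphate isomerase Tpi1 rose by 0.64 ± 0.07, Pgk1 by 0.45, Pgam1 by 0.42 and Gapdh by 0.34. Of 82 ribosomal protein genes, 2 rose (2 adjusted over the list alone), Rps12 by 0.35 and Rps26 by 0.32. That list had a median of 0.13 (camera adjusted p = 3.07e-06). Of 71 nuclear respiratory chain genes, 3 rose, with 0 of them adjusted over the list alone (camera adjusted p = 1.01e-05). The regulatory T cell list had 6 of 17 genes higher and 11 that did not pass (9 higher and 1 lower adjusted over the list alone). Its median was 0.74 (camera adjusted p = 3.07e-05, and adjusted p = 0.116 with an estimated correlation). Of 16 follicular helper and anergy genes, 4 rose (5 adjusted over the list alone; camera adjusted p = 0.000315, and adjusted p = 0.116 with an estimated correlation). Pdcd1 rose by 1.77 and Cd200 by 1.63. Of 28 negative regulators of T cell receptor signalling, 9 rose and 4 fell (10 and 5 adjusted over the list alone; camera adjusted p = 0.0290, and adjusted p = 0.116 with an estimated correlation). Ubash3b rose by 1.09, and Socs3 fell by 1.33. Of 15 BCL2 family genes, 3 rose and 1 fell (6 and 2 adjusted over the list alone; camera adjusted p = 0.0290, and adjusted p = 0.116 with an estimated correlation). Bcl2l11 rose by 0.83 and Bmf was the gene that fell. Leaving out the 3 libraries ended the preset calls of these last 2 lists (camera adjusted p = 0.0638 and 0.0600). The regulatory T cell and the follicular helper and anergy lists were then called with an estimated correlation (camera adjusted p = 0.0381 each).

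NF-kB genes again differed little in RNA by CD5 level in CD8 cells, though most pathway genes leaned lower in CD5hi. Nfkbia was at 351 ± 87.8 CPM in CD5lo and 285 ± 67.3 CPM in CD5hi (log2 change -0.30 ± 0.23, adjusted p = 0.485). The log2 change of Nfkb1 was 0.06 (adjusted p = 0.631) and that of Nfkb2 -0.08 (adjusted p = 0.820). For Rela it was -0.18 (adjusted p = 0.540), for Relb 0.08 (adjusted p = 0.778) and for Rel 0.10 ± 0.34 (adjusted p = 0.907). Of 31 pathway genes, 1 rose and 1 fell, also adjusted over the list alone (median -0.07, camera adjusted p = 0.0753, and adjusted p = 0.644 with an estimated correlation). Only 7 of the 31 had a positive log2 change. With the replicate block, on the partial pairing in CD8, 1 pathway gene rose and 7 fell, and 6 targets rose and 10 fell. Camera with its preset correlation called the pathway list lower without CD8 CD5lo replicate 1. Malt1 rose by 0.35 (adjusted p = 0.0133, and 0.0555 without CD8 CD5lo replicate 4), and Tab1, an adaptor of the kinase TAK1, fell by 0.25 (adjusted p = 0.0171). The call of Tab1 was lost without any of 3 single libraries, with adjusted p up to 0.0615 without CD8 CD5lo replicate 2. Of 34 targets, 3 rose and 3 fell (6 and 5 adjusted over the list alone; camera adjusted p = 0.972), with Tnfrsf9 and Bcl2a1b (0.93) higher and the cytokine Tnf down (fell by 0.76). Of 25 early T cell receptor genes, 1 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.972); Tnfrsf9 rose, and Tnf and the AP-1 gene Jun fell, Jun by 0.70. Of 45 interferon-stimulated genes, 4 fell and 41 did not pass (4 adjusted over the list alone). Camera called the list lower with its preset correlation (adjusted p = 0.0120), a call lost with an estimated correlation (adjusted p = 0.701) and without the 3 libraries (adjusted p = 0.934). Igtp fell by 0.38 and Slfn2 fell by 0.34. Of 22 handling stress genes, 4 fell (4 adjusted over the list alone; camera adjusted p = 0.0299, and adjusted p = 0.600 with an estimated correlation). Of 20 naive and quiescence genes, 2 fell and 1 rose (the same counts adjusted over the list alone; camera adjusted p = 0.0340, adjusted p = 0.644 with an estimated correlation and 0.121 without the 3 libraries). Of the naive genes, Ccr9 fell by 1.19, Btg2 fell by 0.44 and Dapl1 rose by 1.16.

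Many genes moved with CD5 in both lineages. Of the genes tested, 209 were higher in CD5hi in both CD4 and CD8 cells (21.6 expected by chance, odds ratio 28.6, Fisher's exact test, two-sided, p = 4.63e-166). Lower in both were 105 (6.67 expected, odds ratio 43.2, p = 3.47e-104 by the same exact test), and 5 passed in opposite directions. With the 3 libraries rich in B cell markers left out, 229 were higher and 101 lower in both. Kcnf1, Itih5, Chn2, Coro2a, Tnfrsf9, Cd6, Pdcd1, Cd200, Dapl1 and Ubash3b rose in both, and Dntt, Adamts14, Grm6, Slc16a5, Pdlim4, Kcna2, Ccr9, Socs3 and Igtp fell in both. Across genes, log2 changes in CD4 and CD8 correlated with Pearson's r of 0.453 over all 13554 genes (Spearman's rho 0.459) and 0.673 over the 1516 genes that passed in either lineage (rho 0.764), where 89.9% had the same sign. The contrasts share no library, but this does not make them independent. Same-numbered CD4 and CD8 libraries had correlated deviations from group means, from 0.203 to 0.704 at low CD5 and from 0.235 to 0.538 at high CD5. How far this adds to the overlap or to these correlations was not tested. Genes are not independent replicates either. The exact tests allow for neither limit, and no p is given for these correlations. The lower count was 69 without CD4 CD5lo replicate 4.

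**Figure D3:**
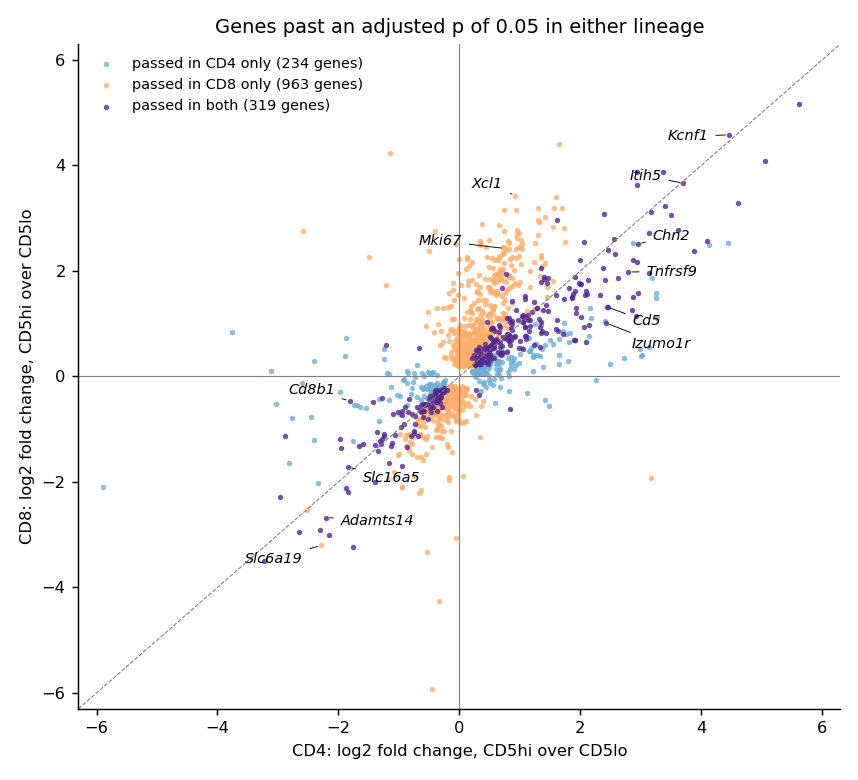
Log2 change from CD5lo to CD5hi in CD4 cells (horizontal axis) and CD8 cells (vertical axis), 1 point for each of the 1516 genes that passed in either lineage, coloured by whether they passed in CD4 alone (234), CD8 alone (963) or both (319); the dashed line marks equal changes. Kcnf1, Itih5 and Chn2 rose in both lineages by 2.51 or more, and Slc6a19 fell by 3.20 in CD8.

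The CD5 effect itself differed between the lineages for 42 genes by the interaction term, and for 379 (205 higher and 174 lower) with the replicate block, on the same partial pairing in CD8. The steps in Cd5 (CD8 minus CD4 -1.13 ± 0.10, edgeR adjusted p = 3.10e-05) and Cd6 (-0.87 ± 0.10, adjusted p = 0.000388) were smaller in CD8 cells. So were those of Izumo1r (-1.42 ± 0.20, adjusted p = 0.00662) and Nt5e (-1.43, adjusted p = 0.0172). Cd8b1 fell less in CD8 than in CD4 cells (1.35 ± 0.11, adjusted p = 1.60e-05). The kinase gene Tec went from 17.0 to 7.76 CPM in CD4 and from 28.3 to 24.6 CPM in CD8 cells (0.93 ± 0.14, adjusted p = 0.0160). These 6 kept their call without any single library, among 17 named genes that passed. The other 11 lost it without at least 1, among them Stmn1 (2.01 ± 0.37, adjusted p = 0.0278, lost without any of 12 libraries, highest 0.0727 without CD8 CD5hi replicate 2). The myosin gene Myo1f was another (1.81 ± 0.29, adjusted p = 0.0172, and 0.0503 without CD8 CD5hi replicate 2). The integrin Itga7 went from 24.7 to 44.3 CPM in CD4 and from 6.75 to 4.40 CPM in CD8 cells (-1.46 ± 0.24, adjusted p = 0.0196, lost without any of 3 libraries, highest 0.0558 without CD8 CD5hi replicate 2). Of 13554 genes, 24 had a positive and 18 a negative difference (CD8 minus CD4), and 89 and 45 without the 3 libraries, which kept 36 of the 42. Single libraries moved these counts. The higher count was 9, 15, 13 and 10 without CD4 CD5lo replicates 1 to 4, and 5, 9, 11 and 10 without CD4 CD5hi replicates 1 to 4. It was 5, 3 and 8 without CD8 CD5lo replicates 1, 2 and 4, and 3, 9 and 108 without CD8 CD5hi replicates 2, 3 and 4. The lower count was 11 without CD4 CD5hi replicate 4, 8 without CD8 CD5lo replicate 2, and 7 and 58 without CD8 CD5hi replicates 2 and 4.

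By gene list, the lineages differed in proliferation and effector genes on one side and regulatory T cell genes on the other, by camera with its preset correlation. It called 9 lists higher and 6 lower (difference CD8 minus CD4), fry called 2 and 4, and camera with an estimated correlation called 0 (4 higher and 4 lower at an unadjusted p under 0.05). The lists called lower were 3 without CD4 CD5lo replicate 4, CD4 CD5hi replicate 2 or 3, or CD8 CD5lo replicate 2 or 3, and 11 without CD8 CD5lo replicate 1. Cell cycle genes had a positive difference, by a median of 1.21 (camera adjusted p = 4.09e-19, and adjusted p = 0.137 with an estimated correlation). None of the 24 passed over all genes in edgeR (22 higher at an unadjusted p under 0.05, 8 by DESeq2 and 0 by limma voom), and 21 did adjusted over the list alone. Of 33 effector and memory genes none passed in edgeR (12 higher and 3 lower at an unadjusted p under 0.05, 6 and 1 by DESeq2, 0 by limma voom). Adjusted over the list alone, 8 were higher and 2 lower (median 1.17, camera adjusted p = 4.14e-06, and adjusted p = 0.121 with an estimated correlation). Tbx21 had a difference of 3.16 (adjusted p = 0.0549). Ribosomal protein genes (camera adjusted p = 4.09e-19), respiratory chain genes (2.23e-07), CD8 lineage genes (8.89e-05), natural killer cell markers (0.00128) and glycolysis genes (0.00179) also had a positive difference, CD8 minus CD4. For these lists adjusted p was 0.223, 0.528, 0.104, 0.104 and 0.187 with an estimated correlation. A negative difference was called for the regulatory T cell list, with 3 of 17 genes lower (6 adjusted over the list alone; median -0.78, camera adjusted p = 1.50e-08, and adjusted p = 0.104 with an estimated correlation). The same held for the follicular helper and anergy list (2 of 16, and 3 adjusted over the list alone; camera adjusted p = 0.000254, and adjusted p = 0.104 with an estimated correlation). It also held for the negative regulators of T cell receptor signalling (1 of 28, Cd6, also adjusted over the list alone; camera adjusted p = 0.0174, and adjusted p = 0.104 with an estimated correlation). For the NF-kB pathway none of 31 genes passed in edgeR (1 lower at an unadjusted p under 0.05, 0 by DESeq2 and 0 by limma voom; median -0.07, camera adjusted p = 0.0273, and adjusted p = 0.518 with an estimated correlation). Nfkbia differed by -0.24 (adjusted p = 0.981) and Nfkb1 by -0.10 (adjusted p = 0.949). The B cell and myeloid markers moved with the lists of positive difference, by medians of 3.03 and 1.57 (camera adjusted p = 0.0273 and 0.0205, and adjusted p = 0.707 and 0.528 with an estimated correlation). Leaving out the 3 libraries ended the preset calls of the negative regulators, B cell and myeloid lists (camera adjusted p = 0.0666, 0.777 and 0.0806). The B cell median was then -0.24, while the cell cycle list had 12 genes higher and a median of 1.43 (adjusted p = 0.0427 with an estimated correlation). Camera with an estimated correlation then also called the regulatory T cell list (adjusted p = 0.00672) and the follicular helper and anergy list (adjusted p = 0.0471) lower.

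**Figure D4:**
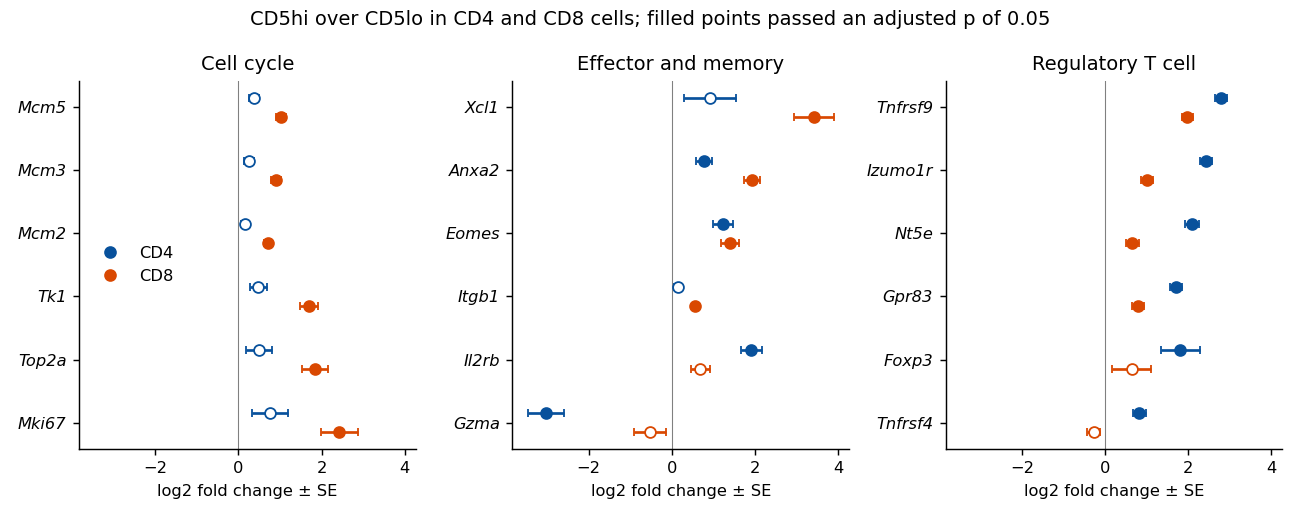
Log2 change from CD5lo to CD5hi (± SE) of cell cycle, effector and regulatory T cell genes in CD4 (blue) and CD8 cells (orange), with filled points for genes that passed. Mki67 rose by 2.42 in CD8, and Izumo1r rose by 2.43 in CD4 and 1.01 in CD8.

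CD4 and CD8 cells differed from each other far more than CD5hi and CD5lo cells did. At low CD5, 1359 genes were higher and 1279 lower in CD8 than in CD4 cells, and at high CD5 2108 and 2003. Without the 3 libraries these were 1131 and 962, and 2220 and 1886, and with the replicate number as a block 2132 and 2213, and 3177 and 3159. In CD5lo cells the largest differences toward CD8 were in Cd8a (8.51 ± 0.50), the integrin Itgae (CD103; 8.03), the cytotoxic granule gene Nkg7 (7.80), Slc6a19 (7.58), the potassium channel Kcnc1 (7.42) and the adhesion receptor Adgrg5 (6.52). Toward CD4 they were in Zbtb7b, the ThPOK factor of the CD4 lineage (-7.30), Cd4 (-7.22), the CD40 ligand gene Cd40lg (-6.93), the sialyltransferase St8sia6 (-4.99), Cdc42bpb (-4.81) and the myosin Myo10 (-4.62). In CD5hi cells Nkg7 (10.49), Cd8a (10.17), Plac8 (9.17), the chemokine receptor Cxcr3 (8.19), Itgae (8.19) and Myo1f (7.56) led toward CD8. Toward CD4 these were Cd4 (-6.00), Zbtb7b (-5.96), St8sia6 (-5.40), Cd40lg (-4.84), Pdlim4 (-4.36) and Myo10 (-4.16). Cd5 was lower in CD8 than in CD4 cells at both levels, by -0.35 ± 0.07 in CD5lo (adjusted p = 0.00166) and -1.48 ± 0.07 in CD5hi (adjusted p = 3.14e-10). Of the NF-kB genes always named, Nfkb1 was lower in CD8 than CD4 cells at high CD5 (-0.19, adjusted p = 0.0213), and Nfkbia, Nfkb2, Rela, Relb and Rel passed at neither level, except that Rela passed at high CD5 with the replicate block (-0.23, adjusted p = 0.0144). Without CD8 CD5lo replicate 3, which held Cd4 at 27.2 CPM, the differences at low CD5 were -9.68 for Cd4, -9.12 for Zbtb7b and -8.39 for Cd40lg. Without CD8 CD5hi replicate 4, which held Cd4 at 62.2 CPM, the differences at high CD5 were -10.81 for Cd4 and -9.17 for Zbtb7b.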

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

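The tests of explanations given here, the splits included, were chosen only after the results were seen, while the test of differences between lineages and the rule for a library far from its group were set before. Other ways of splitting the samples were counted for each comparison. In CD4 cells 1 of 35 splits, the real one, gave 553 or more genes, and the highest of the others gave 0 by edgeR. That is the smallest share 35 splits can give, so chance is made unlikely but not excluded. The other splits also mix libraries of the groups compared, which widens the spread within groups and lowers their counts. For CD8 against CD4 cells it was 1 of 35 at low CD5 (2638, highest other 0) and 1 of 35 at high CD5 (4111, highest other 0). The same limits hold there. Of the 8 splits that part all 4 same-numbered pairs in these 3 comparisons, none but the real one gave more than 0. In CD8 cells 1 of 35 splits, the real one, gave 1282 or more (highest other 20), with the same limits. For the interaction 3 of 100 splits gave 42 genes or more, a share under 0.05. The others of the 3 called more than the real split, however, 98 and 401, so the count of 42 is not set apart from other splits as the counts above are. The split with 401 set replicates 1 and 2 of both CD4 groups against replicates 3 and 4, and CD8 CD5lo replicates 1, 2 and 3 with CD8 CD5hi replicate 1 against the rest of CD8. It keeps each same-numbered pair of CD4 libraries together but parts replicates 2 and 3 of CD8. Whether replicate number accounts for its count was not tested. All these splits were drawn and fitted without the replicate number. With the replicate block 379 genes were called for the interaction, a count that these splits do not judge.

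B cell markers were high in CD4 CD5lo replicate 3, CD8 CD5lo replicate 3 and CD8 CD5hi replicate 4, which the gates for naive CD4+ or CD8+ T cells should have removed. The excess over the 16 markers had nearly the same profile in the 3 libraries (lowest Spearman's rho across genes 0.979), and it came with excess Cd8a of 7.99 CPM, or Cd4 of 25.8 and 61.6 CPM, equal to 0.446, 2.36 and 5.65% of the level in the lineage that owns the gene. These are the values that B cells and other unsorted lymph node cells would bring, and such cells may be their source. Reads carried over from the other 13 libraries cannot account for the Cd74 level, since it reached at most 16.5 CPM there, below each of the 3. Carry-over among the 3 libraries, or of Cd4 and Cd8a reads from libraries of the other lineage, was not tested. The design gives no biological difference between these libraries and the others of their groups, so no biological explanation was tested.

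Cd8b1 was higher in CD4 CD5lo (28.15 CPM) than in CD4 CD5hi (7.996 CPM), in all 4 libraries of each group. CD8 T cells among the sorted CD4 CD5lo cells are excluded as its cause: the lowest ratio of Cd8b1 to Cd8a in CD4 CD5lo was 2.65 (highest 12.6), against 0.575 to 0.683 in CD8 libraries. More recent thymic emigrants in CD4 CD5lo might raise it, as Dntt and Ccr9 were also higher there. This cannot be told from the thymocyte and recent emigrant list, whose members go both ways (camera adjusted p = 0.519). A direct tie to the CD5 level stays open and was not tested.

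Camera called the regulatory T cell list higher in CD4 CD5hi and, with its preset correlation, in CD8 CD5hi, where the call was lost with an estimated correlation (adjusted p = 0.116). Without the 3 libraries rich in B cell markers, camera called it in CD8 with an estimated correlation as well (adjusted p = 0.0381). Of the 3 libraries rich in B cell markers, only CD4 CD5lo replicate 3 belongs to the groups compared in CD4. The CD8 libraries among the 3 enter that comparison through the spread estimated over all 16 samples. In CD4 CD5lo replicate 3 the mean log2 CPM of the list was 2.69, against 1.65 to 1.93 in the other CD4 CD5lo libraries. That library thus worked against the rise. Leaving out the 3 libraries (median 1.68) was thus bound to keep the rise, and it does not test unsorted cells in the other libraries. The 13 members outside the follicular helper and anergy list had a median of 1.42 in CD4, with 8 higher (range -0.88 to 2.79). These 13 belong to a list already called higher, so their rise does not test whether Foxp3-expressing cells lay within the CD4 CD5hi sort. Such cells may contribute, although the gate kept only CD25-negative cells. In CD8 CD5hi this cannot be told: the log2 change of Foxp3 was 0.25 ± 0.22 without the 3 libraries, at most 0.689 by 2 SE, against a median of 0.684 over the 17 members. Higher expression of these genes by naive cells with high CD5 stays open in both lineages and was not tested.

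Single libraries stood far from the other 3 of their group for 48 of 556 groups of values, where chance gives 27.8. Xist, Ddx3y, Cd74 and Foxp3, chosen after their values were seen, are among these groups, so the chance count does not hold for them. The values that follow are the gap to the nearest library as a share of the group's range, for a high value unless low is stated. In CD4 CD5lo, replicate 3 stood apart for Coro2a (0.859), Nkg7 (0.875), Plac8 (0.907), Tk1 (0.869), Xcl1 (0.863) and Cd74 (0.963). Replicate 2 of that group was low for Nfkb1 (0.901) and total counts (0.916), and replicate 4 was high for Xist (0.9995). In CD4 CD5hi, replicate 1 stood apart for Bcl2a1b (0.857) and was low for the regulatory T cell list (0.834), and replicate 2 stood apart for Itih5 (0.905). Replicate 3 did so for Kif23 (0.869), Slc16a3 (0.934) and Trps1 (0.865), and replicate 4 for Xist (0.9997) and, low, Ddx3y (0.846). In CD8 CD5lo, replicate 3 stood apart for Cd4 (0.927), Cd40lg (0.916), Foxp3 (0.909), Il2ra (0.911), Zbtb7b (0.884), Cd74 (0.940) and the myeloid markers (0.864). Replicate 1 was high for Ccr9 (0.912), Ctsw (0.901) and Kif23 (0.855) and low for Mcm2 (0.921). Replicate 4 was low for Bmf (0.9502), Cdh5 (0.8294) and Tk1 (0.832) and high for Xist (0.9988). In CD8 CD5hi, replicate 4 stood apart for Cd4 (0.995), Zbtb7b (0.986), Cd74 (0.980), Il2ra (0.950), Foxp3 (0.871), St8sia6 (0.845), Grm6 (0.931), Pdlim4 (0.904), Cyp2s1 (0.838), Traf1 (0.857) and Xist (0.9994), and was low for Ikzf2 (0.845). It was also high for the myeloid markers (0.976), the CD4 lineage genes (0.843) and the sex-linked genes (0.863). Replicate 2 of that group was high for Tnfrsf9 (0.909).

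The change from CD5lo to CD5hi differed between CD4 and CD8 cells, by the interaction term, for 17 named genes (log2 difference, CD8 minus CD4). It was positive for Stmn1 (2.01), Myo1f (1.81), Cd8b1 (1.35), Sestd1 (1.21), Trps1 (1.21), Car2 (1.20), Kif23 (0.94), Tec (0.93) and Tpi1 (0.59). It was negative for Itga7 (-1.46), Nt5e (-1.43), Izumo1r (-1.42), Cd5 (-1.13), Tnfrsf4 (-1.10), Cd6 (-0.87), Syt11 (-0.73) and Akap12 (-0.68). Of these, 11 lost their call without some single library, with the highest adjusted p for Tnfrsf4 (0.108 without CD8 CD5hi replicate 2). By camera with its preset correlation, 15 lists differed. The difference, CD8 minus CD4, was positive for cell cycle genes (adjusted p = 4.09e-19), ribosomal proteins (4.09e-19), respiratory chain genes (2.23e-07), effector and memory genes (4.14e-06), CD8 lineage genes (8.89e-05), NK cell markers (0.00128), glycolysis genes (0.00179), myeloid markers (0.0205) and B cell markers (0.0273). It was negative for regulatory T cell genes (1.50e-08), follicular helper and anergy genes (0.000254), negative regulators of T cell receptor signalling (0.0174), the NF-kB pathway (0.0273), TCR-induced early genes (0.0376) and thymocyte and recent emigrant genes (0.0401). With an estimated correlation 0 of the 15 were called (adjusted p from 0.104 to 0.707, with 0.528 for the early genes and 0.221 for the thymocyte genes). Without the 3 libraries rich in B cell markers, camera with an estimated correlation called the cell cycle (adjusted p = 0.0427), regulatory T cell (0.00672) and follicular helper and anergy lists (0.0471).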

How the results depend on the processing

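Leaving out the 3 libraries rich in B cell markers, halving the counts, and the block with an estimated correlation were chosen after the data were seen, and the other alternatives before. For named genes, 1682 results under other settings kept their direction and their side of the threshold, 76 no longer passed, 3 passed anew and 1 reversed; with single libraries left out, these were 1622, 305, 0 and 1. The reversal was Cd4 in CD8 CD5hi against CD5lo, 1.04 with all libraries, -1.29 without the 3 libraries and from -3.77 (without CD8 CD5hi replicate 4) to 3.50 with single libraries left out. With RLE size factors, no filter, limma voom and halved counts, all counts of genes stayed within 1.5 times, as did those of DESeq2 except that it called 307 lower in CD4, 128 higher and 87 lower in the interaction, and 178 lower in both lineages. A fit of only the groups compared called 251 lower in CD8. At adjusted p under 0.01, 109 were higher and 46 lower in both lineages. With a term for the replicate number (replicate block), higher and lower counts were 771 and 541 in CD4, 1813 and 1577 in CD8, 205 and 174 for the interaction, 2132 and 2213 between lineages at low CD5, 3177 and 3159 at high CD5, and 490 and 344 in both lineages. Over all 4 groups, 24 pairs with equal numbers correlated from -0.040 to 0.704 across genes after removing group means, 19 of them over 0.1 (median 0.336, against -0.091 for 72 other pairs), so for CD8 CD5hi against CD5lo and the interaction the pairing is not established by every pair. Of 16 libraries, 15 correlated best with one of their own number, a hint of shared sets from the data and not from the design. Xist set replicate 4 apart in every group, both CD8 groups included, a shared trait that the correlation of -0.040 for that CD8 pair does not show. With the block, 13 of 24 cell cycle genes had a positive difference in the interaction (0 without it), and 28 of 71 respiratory chain genes rose in CD8 cells (3 without it). In CD4 cells, 4 genes of proximal T cell receptor signalling and 1 early T cell receptor gene were lower with the block, and 1 interferon-stimulated gene was higher. Counts of list members moved for further lists in CD4. With the block 12 regulatory T cell genes, 8 follicular helper and anergy genes and 5 early T cell receptor genes rose. Of the NF-kB targets 5 rose and 3 fell, of effector and memory genes 6 and 6, and of thymocyte and recent emigrant genes 4 and 2. Interferon-stimulated genes that fell numbered 7. Camera with its preset correlation kept all 10 list calls in CD4 with the block and added the ERK feedback genes. With the block and an estimated correlation together, camera called 2 lists higher and 0 lower in CD4 and 0 either way in CD8 and the interaction. The follicular helper and anergy list (adjusted p = 0.0845) and the BCL2 family (0.108) lost their CD4 calls. Without the 3 libraries, the interaction had 89 higher and 45 lower genes and CD4 9 lists higher. Single libraries left out gave ranges of 518 to 948 higher and 252 to 699 lower in CD8, 3 to 108 higher and 7 to 58 lower for the interaction, and 69 to 121 lower in both lineages. For lists the ranges were 4 to 9 higher in CD4, 1 to 4 lower in CD8 and 3 to 11 lower for the interaction. The lists higher in CD4 were 9 without CD4 CD5lo replicate 3, and those lower in CD8 1 without CD8 CD5lo replicate 3 or CD8 CD5hi replicate 2. For the interaction lower lists were 3 without CD4 CD5lo replicate 4, CD4 CD5hi replicates 2 or 3, or CD8 CD5lo replicates 2 or 3, and 11 without CD8 CD5lo replicate 1. With an estimated correlation camera called 0 lists lower in CD4 (1 at an unadjusted p under 0.05), 0 higher (7) and 0 lower (0) in CD8, and 0 higher (4) and 0 lower (4) for the interaction, and fry called 1 lower in CD4, 1 lower in CD8 and 2 higher for the interaction. For all of these the cause was not tested, except that fewer libraries were fitted where some were left out. Segments of the T cell receptor and technical runs were not run, as 0 such genes were tested and each sample had 1 column. On simulated data, 22.4% of genes with a 1.5-fold and 50.7% with a 2-fold interaction were called, so smaller interactions are often below reach here.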

Other observations

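Few signalling and receptor genes on the remaining lists passed, and on most of these lists they went in both directions. Of 25 genes of proximal T cell receptor signalling, 2 rose and 2 fell in CD4 (2 and 3 adjusted over the list alone, camera adjusted p = 0.982). In CD8 3 fell (1 higher and 4 lower adjusted over the list alone, camera adjusted p = 0.133). Fry called this list lower in CD8 (fry adjusted p = 0.000688) and for the interaction (fry adjusted p = 0.0141). The adaptor Grap2 fell by 0.58 in CD4 and by 0.54 in CD8. Of 22 cytokine receptors, 2 rose and 1 fell in CD4 (3 and 2 adjusted over the list alone; camera adjusted p = 0.757), Il2rb and the shared chain Il6st (0.64) among those higher. In CD8 1 rose and 2 fell (3 and 2 adjusted over the list alone; camera adjusted p = 0.530): Il10ra rose by 0.51 and Tnfrsf1a fell by 0.43. Of 26 chemokine receptors and adhesion molecules, 1 rose and 1 fell in CD4 (3 and 1 adjusted over the list alone; camera adjusted p = 0.925), and 3 rose and 2 fell in CD8 (5 and 5 adjusted over the list alone; camera adjusted p = 0.972). Among 13 ERK feedback genes, 11 had a positive log2 change in each lineage. Etv5 alone passed, by 0.83 in CD4 and 0.66 in CD8 (also adjusted over the list alone, camera adjusted p = 0.0551 and 0.182). Its call was lost without CD4 CD5hi replicate 4 in CD4 (adjusted p = 0.0563), and in CD8 without any of 5 libraries (highest 0.0928 without CD8 CD5hi replicate 2). Of 13 thymocyte and recent emigrant genes, 3 rose and 2 fell in CD4 (4 and 2 adjusted over the list alone), and 2 rose and 3 fell in CD8 (2 and 5 adjusted over the list alone; camera adjusted p = 0.359). The developmental factor Tox rose by 0.57 in CD4, and Arpp21 fell by 1.91 in CD8. With the replicate block in CD4, 2 ERK feedback genes rose (camera adjusted p = 0.0305, and adjusted p = 0.241 with an estimated correlation), 3 cytokine receptors rose and 4 fell, and 4 chemokine receptors and adhesion molecules rose and 2 fell.

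Chromatin, lipid and histone genes changed in few members. Of 30 chromatin regulators, 1 rose and 1 fell in CD4 (also adjusted over the list alone; camera adjusted p = 0.815), and 2 rose in CD8 (1 adjusted over the list alone; camera adjusted p = 0.303). The deacetylase Hdac7 fell by 0.47 in CD4, and the DNA methyltransferase Dnmt3a rose by 0.43 in CD8. Of 40 replication-dependent histones, 4 fell in CD8 (5 adjusted over the list alone; camera adjusted p = 0.123), each with a call lost without at least 1 library, and none passed in CD4 by edgeR (2 lower at an unadjusted p under 0.05, 1 by DESeq2, 0 by limma voom; camera adjusted p = 0.465). Of 24 cholesterol and lipid synthesis genes, 1 rose in CD4 (also adjusted over the list alone; camera adjusted p = 0.533), and 2 rose and 1 fell in CD8 (also adjusted over the list alone; camera adjusted p = 0.530). In CD4, 1 of 17 glycolysis genes rose, the lactate transporter Slc16a3 by 1.21 (also adjusted over the list alone; camera adjusted p = 0.0629). None of 71 respiratory chain genes passed there by edgeR (0 at an unadjusted p under 0.05, 0 by DESeq2, 0 by limma voom; camera adjusted p = 0.982). Of 20 naive and quiescence genes, 1 rose and 2 fell in CD4 (also adjusted over the list alone; camera adjusted p = 0.757). Dapl1 rose by 1.13 there. With the replicate block 2 naive and quiescence genes rose and 3 fell in CD4, and 2 histone genes fell.

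Markers of other cells were as follows. Of 7 NK cell markers, 1 rose and 2 fell in CD4 (1 and 3 adjusted over the list alone), and 2 rose in CD8, Klrb1c by 1.86 and Cd160 by 1.04 (2 adjusted over the list alone; camera adjusted p = 0.386). Of 6 gamma-delta and innate-like T cell markers, Klrb1c alone rose in CD8 (also adjusted over the list alone; camera adjusted p = 0.386), and none passed in CD4 by edgeR (0 at an unadjusted p under 0.05, 0 by DESeq2, 0 by limma voom; camera adjusted p = 0.982). Of 5 stromal and endothelial markers, Col1a1 rose by 1.42 in CD4 (camera adjusted p = 0.151), a call lost without any of 5 libraries (highest adjusted p 0.0761 without CD4 CD5lo replicate 2). Cdh5 rose by 1.23 in CD8, a call lost without CD8 CD5hi replicate 2 (adjusted p = 0.0575), on a list with a median of -0.45 (camera adjusted p = 0.715). Of 6 CD4 lineage genes, Tnfrsf25 alone rose, by 0.40 in CD4 (camera adjusted p = 0.506) and 0.54 in CD8 (2 higher adjusted over the list alone; camera adjusted p = 0.182). The call in CD4 was lost without any of 5 libraries (highest adjusted p 0.101 without CD4 CD5hi replicate 1). Of 8 CD8 lineage genes, 1 rose and 1 fell in CD8, the cathepsin Ctsw by 0.58 and Cd8b1, which fell by 0.47 (also adjusted over the list alone; camera adjusted p = 0.409).

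Sex-linked genes, looked at after their values were seen, set replicate 4 apart in every group. Xist was at 224.7, 248 and 258.9 CPM in replicate 4 of CD4 CD5lo, CD4 CD5hi and CD8 CD5lo and at 234.9 CPM in that of CD8 CD5hi, against at most 0.351 CPM in the other 12 libraries. The Y-linked Ddx3y was at 59.3, 47.9, 47.2 and 49.1 CPM in the same libraries and at 91.6 to 126.2 CPM in the others. The sex of the mice is not given in the sources used here. Of 5 sex-linked genes none passed by edgeR in CD4 or CD8 (0 at an unadjusted p under 0.05, 0 by DESeq2, 0 by limma voom; camera adjusted p = 0.955 and 0.972).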
